A study of Rattus norvegicus with 36 samples.

How the data were processed

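The study measured liver RNA of male Harlan Sprague Dawley rats given PBDE47 (2,2',4,4'-tetrabromodiphenyl ether, a flame retardant) in corn oil by oral gavage on 5 consecutive days. Per the labels, 36 livers were measured on 36 Affymetrix rat expression arrays, 1 array per animal, with 6 arrays for vehicle and 6 for each of 5 doses (485 mg/kg as the highest, then 48.5, 4.85, 0.485 and, lowest, 0.0485 mg/kg). The label protocol gives the 3' IVT Plus kit for amplification and biotin labelling.

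The deposited table holds log2 values, 1 per probe set and array, made by the authors with RMA and the R package affy, whose versions were not given. RMA corrects background, quantile normalizes the probes between arrays and summarizes each probe set by median polish, so a value is relative to a distribution shared by all arrays. The medians of the 36 arrays lay between 5.31 and 5.38 and the highest values between 15.0 and 15.1. No depth exists for an array, and the number of arrays limits the precision. No 2 arrays held identical values, and the correlation of arrays within a group, across probe sets, ran from 0.990 to 0.997.

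Of 31099 probe sets, 57 control probe sets were left out of the tests and 31042 were tested with no filter on level. The platform table assigned 20826 of these to a single gene and 436 to several genes, and 9780 were treated as unnamed here. The Entrez identifiers of 20758 single-gene probe sets matched the RefSeq gene table of the GRCr8 assembly, 68 kept the platform symbol, and 0 symbols changed. The names covered 14217 genes. A gene was represented by the probe set with the highest mean over all 36 arrays among those assigned to it alone. Cyp2b1 and Cyp2b2 share the probe set 1371076_at and have none of their own on this platform table, so their joint value is reported as the CYP2B joint probe set.

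The main test was a one-way linear model over all 36 arrays in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 30 residual and 5.26 prior degrees of freedom. Each dose was compared with vehicle, and 485 with 48.5 mg/kg, two-sided. Adjusted p values come from limma with Benjamini-Hochberg adjustment over 31042 probe sets within a comparison, and a probe set was called at an adjusted p below 0.05. A moderated F test covered the 5 contrasts together, and a model over 24 arrays tested a trend with the dose step from vehicle to 4.85 mg/kg. The study named the R/maanova package with a false discovery rate under 5% for its own tests. That package was not used here, and the ordinary test of the same linear model, without moderation, stood in as an alternative.

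Before the data were examined, 35 gene lists were fixed (22 pathway lists and 13 lists of cell type markers), along with the tests, the alternatives and the rule for named genes. A list was tested with limma's camera at a preset correlation of 0.01 between genes, on representative probe sets, with adjustment over 35 lists per comparison. Camera with an estimated correlation and fry, limma's rotation test of a list's own genes, were alternatives. The counts "adjusted over the list alone" use only the list's genes in the Benjamini-Hochberg adjustment.

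The rule named, at every dose, a panel of 12 genes of drug metabolism, thyroid hormone response and bile acid synthesis. At 48.5 and 485 mg/kg it added the 10 largest rises and the 10 largest falls among called genes whose 6 treated arrays all lay outside the range of the 6 vehicle arrays, and elsewhere the 5 largest of each. From each list it took up to 4 called members with the largest change; 3 were used at 485 mg/kg and 2 elsewhere. Probe sets assigned to no gene or to several genes were counted and, apart from the CYP2B joint probe set, not named.

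Alternatives changed 1 choice at a time: the replicate number as a block, quantile normalization of the deposited values, centring of each array on its median, a filter keeping 16024 brighter probe sets, the ordinary test, eBayes with trend and robust settings, array quality weights, only the 12 arrays compared, a minimum change of 1.5-fold, the mean of a gene's probe sets, and each array left out in turn. A fit without the array of 4.85 mg/kg replicate 6 was added after its values were seen. The overlap of the 48.5 and 485 mg/kg calls was set beside independent lists and splits of the vehicle arrays, and the correlation of their log2 changes beside 100 simulated draws of unchanged groups sharing their controls. Every count of calls was compared with 100 random splits of its arrays. RNA quality and array structure were checked by exact permutation tests on the difference between 3' and 5' control probe sets of Gapdh, Actb and hexokinase and on principal components.

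The procedure was tested on simulated data with known changes. In a simulated comparison of 485 mg/kg with vehicle, 200 of 31042 probe sets were changed. Of 50 given a log2 change of 0.5, 90% were called, and of 50 given 0.25, 32%. Unchanged probe sets made up 9 calls, 5.33% of the calls. These shares do not carry over to doses with few or no calls, where the adjustment is stricter. At 4.85 mg/kg Cyp3a23-3a1 was not called at a log2 change of 0.46 (limma unadjusted p = 8.03e-05, adjusted p = 0.169). In 20 draws with no dose effect, camera at the preset correlation called a median of 4 and at most 9 of 35 lists, while the estimated correlation and fry each called a median of 0 and at most 1. With a log2 shift of 0.5 added, the shifted list was called in 20 of 20 draws by camera with either correlation. Tables were handled with pandas 2.3.3 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.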

Results

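Liver expression was measured in 36 male rats after 5 daily doses of PBDE47 or of the corn oil vehicle, with 6 animals in each of 6 groups. PBDE47 is a brominated flame retardant. Values are log2 RMA values of 31042 probe sets, and each change below is a log2 difference from vehicle with its standard error (SE) from limma, with n = 6 animals per group. Group levels are given as mean ± SD. No detection call was made, so a fold is not exact where a group mean lay below the lowest array median of 5.31. Among named genes called in a comparison this held for Cyp1a1, Abcc3, Cyp4a8, Gadd45b, Ttc39a, Ccna2 and Mki67, whose rises can be larger than stated, and for Car1, Cd8a, Nim1k and Abcg8, whose falls can be larger. The question was which liver transcripts change at each dose relative to vehicle, over doses spaced by steps of the same factor from 0.0485 to 485 mg/kg.

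The liver response grew with dose, from 0 called probe sets at the 2 lowest doses to 6 at 4.85 mg/kg, 1052 at 48.5 mg/kg and 4665 at 485 mg/kg. Genes for drug-metabolizing enzymes and transporters led the response at each dose with calls. The CYP2B joint probe set (1371076_at), shared by the phenobarbital-type cytochrome P450 genes Cyp2b1 and Cyp2b2, rose from 10.79 ± 0.41 in vehicle to 12.97 ± 0.16 at 4.85 mg/kg, 14.25 ± 0.05 at 48.5 mg/kg and 14.44 ± 0.07 at 485 mg/kg. Over all 5 doses together, 4041 probe sets of 2606 genes differed among the 6 groups by the moderated F test (adjusted p below 0.05).

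**Figure D1:**
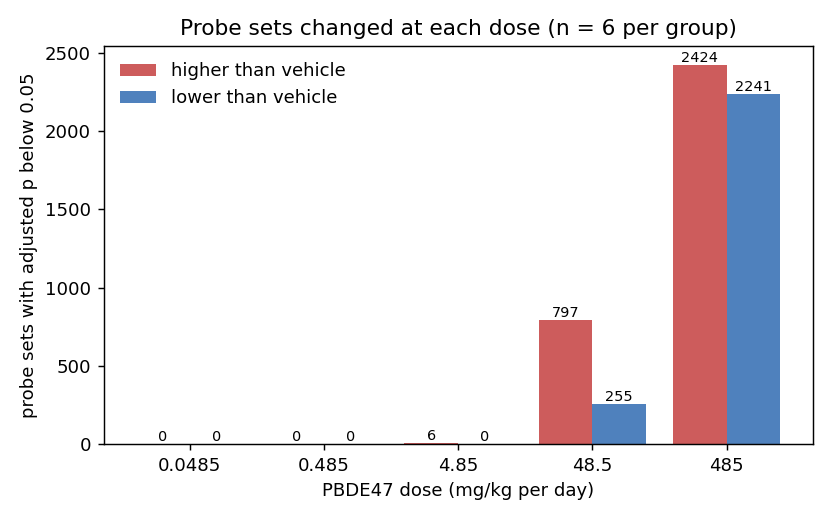
Number of probe sets called higher (red) or lower (blue) than vehicle at each PBDE47 dose, by limma at an adjusted p below 0.05 with n = 6 per group. The bars are at 0 for the 2 lowest doses and reach 2424 higher and 2241 lower at 485 mg/kg.

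At 0.0485 mg/kg no gene of the drug metabolism panel passed the test. The log2 change was -0.09 ± 0.17 SE for the CYP2B joint probe set, -0.06 ± 0.10 for Cyp3a23-3a1, 0.24 ± 0.11 for Ugt2b1, 0.30 ± 0.15 for Abcc3, -0.16 ± 0.08 for Cyp1a2 and 0.06 ± 0.12 for Nqo1, while Cyp1a1 stood at 4.82 in both groups. It was 0.08 ± 0.31 for Thrsp and -0.07 ± 0.09 for Dio1, both regulated by thyroid hormone, 0.61 ± 0.27 for Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and -0.12 ± 0.06 for Cyp2c11, a male-specific cytochrome P450. Limma called 0 of 31042 probe sets, with 1519 at an unadjusted p under 0.05 (4.89% of those tested), and the ordinary test, the fit on 12 arrays and the weighted fit also gave 0.

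Among the gene lists at 0.0485 mg/kg, camera at the preset correlation called 5 of 35. The lists of PPARA targets and fatty acid oxidation (median log2 change 0.10, adjusted p = 0.00431), cholesterol synthesis (0.10, adjusted p = 0.0285) and bile acid synthesis and transport (0.08, adjusted p = 0.0285) were called higher. Cell cycle genes (-0.06, adjusted p = 0.0304) and cholangiocyte markers (-0.12, adjusted p = 0.0413) were called lower. None of these lists held a called gene, also when adjusted over the list alone, and with an estimated correlation the adjusted p was 0.523, 0.731, 0.493, 0.652 and 0.493 in that order. Simulated groups without an effect gave a median of 4 called lists under the same setting, so this number lies at the level of chance.

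At 0.485 mg/kg the panel again held no call. The log2 change was 0.40 ± 0.17 SE for the CYP2B joint probe set and 0.44 ± 0.15 for Abcc3, and it was -0.01 ± 0.10 for Cyp3a23-3a1, 0.13 ± 0.11 for Ugt2b1, 0.22 ± 0.26 for Cyp1a1, -0.10 ± 0.08 for Cyp1a2 and -0.03 ± 0.12 for Nqo1. It was 0.42 ± 0.31 for Thrsp, 0.08 ± 0.09 for Dio1, 0.47 ± 0.27 for Cyp7a1 and -0.07 ± 0.06 for Cyp2c11. Limma called 0 of 31042 probe sets, with 1381 at an unadjusted p under 0.05 (4.45%), and the ordinary test, the fit on 12 arrays and the weighted fit also gave 0.

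Of the gene lists at 0.485 mg/kg, camera at the preset correlation called 5, again near the median of 4 in simulated groups without an effect. Called higher were cholesterol synthesis and uptake (median log2 change 0.21, adjusted p = 8.5e-10), lipogenesis (0.12, adjusted p = 0.000819) and the ER stress and amino acid response list (0.13, adjusted p = 0.000569). Interferon and antigen presentation genes (-0.33, adjusted p = 2.43e-06) and T and NK cell markers (-0.12, adjusted p = 0.00667) were called lower. The mean of the interferon list medians per animal was -0.38 at this dose and -0.21 without replicate 3, against 0.01 in vehicle. No member of these lists was called, nor when adjusted over the list alone, and with an estimated correlation the adjusted p was 0.424, 0.536, 0.424, 0.507 and 0.424 in that order.

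At 4.85 mg/kg 6 probe sets rose and 0 fell, and all 6 were also called higher at 48.5 and 485 mg/kg. Signal of the CYP2B joint probe set rose 4.51-fold (log2 2.17 ± 0.17 SE, adjusted p = 2.83e-10). Abcc3 (1369698_at), an efflux transporter of conjugates at the basolateral side of hepatocytes, rose 2.09-fold (1.06 ± 0.15, adjusted p = 0.000262). The other genes were Ugt2b1 (1370698_at), a UDP-glucuronosyltransferase, at 1.69-fold (0.76 ± 0.11, adjusted p = 0.00049), Ces2c (1368905_at), a carboxylesterase, at 1.68-fold (0.75 ± 0.13, adjusted p = 0.0154), Aldh1a1 (1387022_at), a retinaldehyde dehydrogenase, at 1.47-fold (0.55 ± 0.09, adjusted p = 0.00138) and Cyp2c6v1 (1370580_a_at), a cytochrome P450, at 1.20-fold (0.27 ± 0.04, adjusted p = 0.00308).

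The remaining panel genes did not pass at 4.85 mg/kg. The log2 change was 0.46 ± 0.10 for Cyp3a23-3a1 (adjusted p = 0.169), 0.48 ± 0.12 for Nqo1 (adjusted p = 0.29), 0.39 ± 0.26 for Cyp1a1 (adjusted p = 0.872) and 0.03 ± 0.08 for Cyp1a2 (adjusted p = 0.987). It was -0.02 ± 0.31 for Thrsp, 0.01 ± 0.09 for Dio1, 0.45 ± 0.27 for Cyp7a1 and 0.11 ± 0.06 for Cyp2c11, with adjusted p values of 0.995, 0.995, 0.852 and 0.834. The list of CAR and PXR target genes, the xenobiotic receptors that drive drug metabolism, was shifted upward with 5 of 22 measured genes called higher, 11 when adjusted over the list alone, and 0 lower (median log2 change 0.28, camera adjusted p = 2.37e-18, adjusted p = 0.00255 with an estimated correlation). At this dose 2006 probe sets had an unadjusted p under 0.05, and a fit on the 12 arrays of this dose and vehicle alone called 1.

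Camera at the preset correlation called 5 other lists at 4.85 mg/kg, and none of these calls held with an estimated correlation. Fry called only the NRF2 list among them (adjusted p = 0.0477). NRF2 and glutathione genes had a median log2 change of 0.15 (adjusted p = 5.57e-07, adjusted p = 0.138 with an estimated correlation), with 0 members called and 6 called higher when adjusted over the list alone. Interferon and antigen presentation genes had a median of -0.36 (adjusted p = 5.57e-07, and 0.587 with an estimated correlation). Replicates 5 and 6 carried most of this shift, since the mean of the list medians per animal was -0.50 with them and -0.07 without them. The others were cholesterol synthesis and uptake (0.13, adjusted p = 0.00603, and 0.817 with an estimated correlation), PPARA targets and fatty acid oxidation (0.07, adjusted p = 0.0306, and 0.809) and heme synthesis and degradation (0.06, adjusted p = 0.0307, and 0.495). Heme genes held 1 call when adjusted over the list alone, and the other 3 lists held 0. The fit without replicate 6 of this group, whose array stood apart from the others, called 5 probe sets and 5 lists.

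Across vehicle and the 3 lowest doses, 2 probe sets showed a trend with the dose step. The fitted slope was 0.70 in log2 per step for the CYP2B joint probe set (adjusted p = 0.0059) and 0.33 for Abcc3 (adjusted p = 0.0109). Neither rise was even over the steps. From 0.0485 to 4.85 mg/kg the changes from vehicle were -0.09, 0.40 and 2.17 for the CYP2B joint probe set, and 0.30, 0.44 and 1.06 for Abcc3. The largest step was thus that to 4.85 mg/kg, where both were already called. At an unadjusted p under 0.05 stood 1740 probe sets. The count was 1 without vehicle replicate 2, 1 without 4.85 mg/kg replicate 4 and 0 by the ordinary test.

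**Figure D2:**
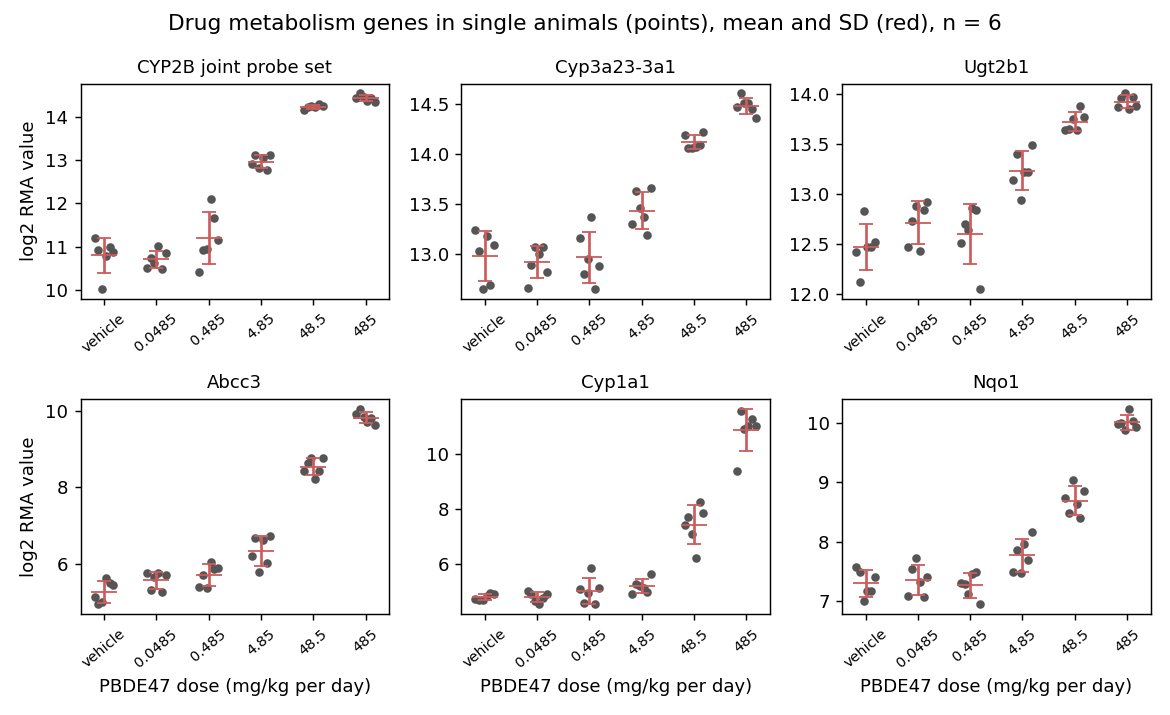
Log2 RMA values of 6 drug metabolism genes in single animals (grey points), with the group mean and SD in red, for vehicle and each PBDE47 dose in mg/kg (n = 6). Signal of the CYP2B joint probe set is at 12.97 ± 0.16 at 4.85 mg/kg against 10.79 ± 0.41 in vehicle, and Cyp1a1 is at 7.43 ± 0.70 at 48.5 mg/kg against 4.82 ± 0.11.

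At 48.5 mg/kg 797 probe sets rose and 255 fell, covering 727 genes, and enzymes and transporters of drug metabolism led the rises. The CYP2B joint probe set rose 10.9-fold (log2 3.45 ± 0.17 SE, adjusted p = 8.24e-17), Abcc3 rose 9.62-fold (3.27 ± 0.15, adjusted p = 6.75e-18) and Ces2c rose 6.00-fold (2.58 ± 0.13, adjusted p = 3.37e-16). Cyp1a1 (1370269_at), the classic target of the aryl hydrocarbon receptor AhR, rose 6.11-fold (2.61 ± 0.26, adjusted p = 1.15e-08), and the glutathione transferase Gsta3 (1371089_at) rose 3.98-fold (1.99 ± 0.17, adjusted p = 3.54e-10). The largest fall was that of Lox (1368171_at), lysyl oxidase, which crosslinks collagen, at 5.33-fold lower (-2.41 ± 0.40, adjusted p = 0.000207).

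Other large rises at 48.5 mg/kg were those of Snx10, a sorting nexin (3.53-fold, 1.82 ± 0.23), Cyp4a8, a fatty acid hydroxylase (3.32-fold, 1.73 ± 0.21), Cyp3a9 (3.24-fold, 1.70 ± 0.26), Hdc, which makes histamine (3.19-fold, 1.67 ± 0.29), Alas1, the rate-limiting enzyme of heme synthesis (2.73-fold, 1.45 ± 0.18), and Nqo1, a quinone reductase (2.64-fold, 1.40 ± 0.12). In the panel, Cyp3a23-3a1 rose 2.21-fold (1.14 ± 0.10) and Ugt2b1 rose 2.38-fold (1.25 ± 0.11). Cyp1a2 (0.20 ± 0.08, adjusted p = 0.173), Thrsp (0.28 ± 0.31, adjusted p = 0.728), Dio1 (-0.03 ± 0.09, adjusted p = 0.92), Cyp2c11 (0.16 ± 0.06, adjusted p = 0.178) and Cyp7a1 (0.81 ± 0.27, adjusted p = 0.104) did not pass. The adjusted p for Cyp7a1 at 48.5 mg/kg was 0.0474 with the replicate number as a block, and its alternatives ran from there to 0.115.

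Other genes fell at 48.5 mg/kg. Socs2 fell 3.27-fold (-1.71 ± 0.43, adjusted p = 0.0196) and the fatty acid desaturase Scd fell 3.06-fold (-1.61 ± 0.45, adjusted p = 0.0347). Sgk1, a kinase induced by glucocorticoids, fell 2.24-fold (-1.16 ± 0.29). The complement gene C6 (-0.69 ± 0.19), the carbonic anhydrase Car1 (-0.66 ± 0.10), the trypsin inhibitor gene Spink1 (-0.62 ± 0.16) and its relative Spink1l (-0.70 ± 0.13), liver glutaminase Gls2 (-0.62 ± 0.10), Dexi (-0.60 ± 0.08), the disulfide isomerase Pdia5 (-0.60 ± 0.14) and the adenylate kinase Ak4 (-0.58 ± 0.10) also fell, with adjusted p values from 3.76e-06 to 0.039. At an unadjusted p under 0.05 stood 4826 probe sets. The number of probe sets changed at 48.5 mg/kg was 678 without replicate 5 of this dose, 556 in a fit on the 12 arrays of this dose and vehicle, and 150 with a minimum change of 1.5-fold.

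Camera at the preset correlation called 11 lists at 48.5 mg/kg, 6 higher and 5 lower. CAR and PXR targets rose with 17 of 22 genes called higher and 0 lower, 18 when adjusted over the list alone (median 0.74, adjusted p = 1.94e-33, and 2.67e-05 with an estimated correlation). NRF2 and glutathione genes rose with 13 of 25 higher and 0 lower, 18 when adjusted over the list alone (0.42, adjusted p = 1.76e-19, and 0.000689 with an estimated correlation), led by Gsta3 and Nqo1. Periportal hepatocyte markers fell with 3 of 8 lower and 0 higher, 4 when adjusted over the list alone (-0.41, adjusted p = 0.000464, and 0.026 with an estimated correlation), among them the serine dehydratase Sds (-1.16 ± 0.30, adjusted p = 0.0221) and Gls2.

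The other 8 calls did not hold with an estimated correlation. Fry called the lists of AhR targets (adjusted p = 7.53e-06), glucuronidation (4.3e-05), urea cycle (0.00186) and heme genes (0.00137), and hepatocyte (0.000519) and T and NK cell markers (0.0173). It did not call cell cycle (0.116) or interferon genes (0.263). AhR targets had 2 of 7 genes higher, Cyp1a1 and Nqo1, and 3 when adjusted over the list alone (median 0.02, mean 0.57, adjusted p = 0.0142, and 0.126 with an estimated correlation). Glucuronidation and sulfation enzymes had 4 of 18 higher, 6 higher and 1 lower when adjusted over the list alone, led by Ugt2b1 and Ugt2b10 (0.59 ± 0.08). Their median of -0.01 and mean of 0.12 differ in sign, and the test pointed upward (adjusted p = 0.0425, and 0.165 with an estimated correlation). The urea cycle and amino acid catabolism list had 5 of 20 genes lower and 1 higher, 7 and 1 when adjusted over the list alone (median -0.11, adjusted p = 8.21e-05, and 0.165 with an estimated correlation), with ornithine aminotransferase Oat lower by 2.12-fold (-1.09 ± 0.19, adjusted p = 0.000367). Heme synthesis and degradation had 2 of 10 higher under both adjustments, Alas1 and the biliverdin reductase Blvrb (0.57 ± 0.06, adjusted p = 3.59e-08), with a list adjusted p of 0.0425, and 0.31 with an estimated correlation. Cell cycle genes had 2 of 25 higher, 4 when adjusted over the list alone (median 0.14, adjusted p = 0.0159, and 0.495 with an estimated correlation), led by the replication factor Mcm2 (0.35 ± 0.09).

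Interferon and antigen presentation genes at 48.5 mg/kg had a median of -0.37 with 0 of 17 called under both adjustments (adjusted p = 0.00357, and 0.513 with an estimated correlation). The mean of their list medians per animal was -0.36, and -0.19 without replicate 3. T and NK cell markers had 1 of 10 lower, Cd8a (-0.43 ± 0.10, adjusted p = 0.00978), also when adjusted over the list alone (median -0.15, adjusted p = 0.00533, and 0.232 with an estimated correlation). Hepatocyte markers had 1 of 9 lower, also when adjusted over the list alone (median -0.04, adjusted p = 0.0425, and 0.232 with an estimated correlation). That gene was the fibrinogen gene Fgb (-0.14 ± 0.04, adjusted p = 0.0358), whose call was lost after median centring (0.0885) and with the mean of its 3 probe sets (0.297), with the lowest of its alternatives at 0.0449. The Kupffer cell and macrophage list stood at a median of -0.18 with 0 of 9 called (adjusted p = 0.0617).

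At 485 mg/kg 2424 probe sets rose and 2241 fell, covering 2971 genes, with 146 rises and 89 falls of at least 2-fold. Cyp1a1 rose 65.5-fold (log2 6.03 ± 0.26 SE, adjusted p = 3.53e-19) from a vehicle level of 4.82, Abcc3 rose 23.4-fold (4.55 ± 0.15, adjusted p = 4.98e-23), Ces2c rose 18.5-fold (4.21 ± 0.13, adjusted p = 4.98e-23) and Gsta3 rose 13.9-fold (3.79 ± 0.17, adjusted p = 1.18e-18). At this dose the CYP2B joint probe set was 12.5-fold above vehicle (3.65 ± 0.17, adjusted p = 3.05e-18). The largest falls were those of Stac3 (1395403_at), known as an adaptor of the muscle calcium channel, at 8.70-fold lower (-3.12 ± 0.39, adjusted p = 1.54e-07), Lox at 7.71-fold lower (-2.95 ± 0.40, adjusted p = 7.66e-07), and Dhrs7l1 (1397205_at), of the short-chain dehydrogenase family, at 7.02-fold lower (-2.81 ± 0.33, adjusted p = 5.44e-08).

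Further large rises at 485 mg/kg were those of the palmitoyltransferase Zdhhc2 (7.17-fold, 2.84 ± 0.12), Nqo1 (6.62-fold, 2.73 ± 0.12), Snx10 (6.35-fold, 2.67 ± 0.23), the glutathione transferase Gstt3 (5.31-fold, 2.41 ± 0.16), the stress-response gene Gadd45b (5.26-fold, 2.39 ± 0.21) and Ttc39a (4.84-fold, 2.28 ± 0.13). Further large falls were those of Serpina7, thyroxine-binding globulin (6.12-fold lower, -2.61 ± 0.35), the taurine transporter Slc6a6 (-2.49 ± 0.40), the kinase Nim1k (-2.44 ± 0.37), Abcg8, which exports sterols into bile (-2.22 ± 0.27), the acute phase protein A2m (-2.21 ± 0.31), Socs2, a feedback inhibitor of growth hormone signalling (-2.11 ± 0.43), and the NADPH oxidase Nox4 (4.01-fold lower). Their adjusted p values ran from 2.69e-19 to 0.0005. In the panel, Cyp3a23-3a1 rose 2.84-fold (1.51 ± 0.10), Ugt2b1 rose 2.73-fold (1.45 ± 0.11) and Cyp1a2 rose 1.23-fold (0.30 ± 0.08, adjusted p = 0.00475).

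Dio1, the deiodinase that activates thyroxine, fell by 0.25 ± 0.09 in log2 at 485 mg/kg (adjusted p = 0.0485), and this call was lost under each of its 3 alternatives, at 0.0553 to 0.0766. Thrsp (0.44 ± 0.31, adjusted p = 0.4), Cyp7a1 (0.41 ± 0.27, adjusted p = 0.375) and Cyp2c11 (-0.04 ± 0.06, adjusted p = 0.77) did not pass. At an unadjusted p under 0.05 stood 8026 probe sets. With a minimum change of 1.5-fold the number of probe sets changed at 485 mg/kg was 797.

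Camera at the preset correlation called 20 of 35 lists at 485 mg/kg, 9 higher and 11 lower, and 5 of these held with an estimated correlation. CAR and PXR targets rose with 20 of 22 genes higher and 0 lower, 21 when adjusted over the list alone (median 1.22, adjusted p = 1.54e-30, and 3.08e-05 with an estimated correlation). NRF2 and glutathione genes rose with 22 of 25 higher and 0 lower, also when adjusted over the list alone (0.81, adjusted p = 1.54e-30, and 3.08e-05 with an estimated correlation), among them Gsta3, Nqo1 and the glutathione reductase Gsr (3.65-fold, 1.87 ± 0.10). Glucuronidation and sulfation enzymes had 10 of 18 higher and 4 lower under both adjustments (0.30, adjusted p = 0.00356, and 0.0323 with an estimated correlation). The sulfotransferase Sult2a6 rose 4.73-fold (2.24 ± 0.30) while another sulfotransferase, Sult1c2, fell 2.65-fold (-1.41 ± 0.15). AhR targets had 3 of 7 higher, Cyp1a1, Nqo1 and Cyp1a2, and 3 higher and 1 lower when adjusted over the list alone (median 0.07, mean 1.24, adjusted p = 0.00982, and 0.069 with an estimated correlation).

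The lists of nutrient metabolism at 485 mg/kg went in both directions. In the urea cycle and amino acid catabolism list 10 of 20 genes fell and 1 rose, 13 and 2 when adjusted over the list alone (median -0.30, adjusted p = 3.77e-05, and 0.071 with an estimated correlation), with Oat at -1.80 ± 0.19, Sds at -1.11 ± 0.30 and histidine ammonia-lyase Hal at -0.95 ± 0.15. Of the gluconeogenesis and glucose metabolism list 7 of 15 fell and 0 rose, 7 and 1 when adjusted over the list alone (-0.22, adjusted p = 0.00486, and 0.0885 with an estimated correlation), with Igfbp1 (-1.95 ± 0.50), which binds insulin-like growth factors, and Pck1 (-1.36 ± 0.23), the entry enzyme of gluconeogenesis. PPARA targets and fatty acid oxidation genes had 8 of 33 higher and 5 lower, 14 and 5 when adjusted over the list alone (0.09, adjusted p = 0.033, and 0.439 with an estimated correlation). In that list Cyp4a8 (2.12 ± 0.21) and the thioesterase Acot2 (0.69 ± 0.12) rose, and Cpt1a, which controls fatty acid entry into mitochondria, fell (-0.83 ± 0.17). Bile acid synthesis and transport genes had 4 of 21 higher and 8 lower, 4 and 9 when adjusted over the list alone (-0.12, adjusted p = 0.0411, and 0.284 with an estimated correlation), with Abcc3 higher and the sterol exporters Abcg8 and Abcg5 (3.99-fold lower) lower.

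Lipid synthesis lists were not called at 485 mg/kg. Lipogenesis had 4 of 20 genes higher and 3 lower under both adjustments (median 0.08, adjusted p = 0.487). The elongase Elovl6 (1.66 ± 0.30) and the malic enzyme Me1 (1.64 ± 0.12) rose while the desaturase Fads2 fell (-1.16 ± 0.16). Cholesterol synthesis and uptake had 2 of 20 higher under both adjustments (0.10, adjusted p = 0.303), Sc5d (0.40 ± 0.07) and Fdft1 (0.33 ± 0.10, adjusted p = 0.0281). The call of Fdft1 was lost after quantile normalization (adjusted p = 0.0706), and its alternatives ran from 0.0154.

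Lists of hormone-responsive and acute phase genes at 485 mg/kg held no camera call that was kept with an estimated correlation. Fry, which tests a list's own genes, called the growth hormone (adjusted p = 6.68e-07), thyroid hormone (0.000115) and acute phase lists (8.33e-11) lower. The list of male-predominant and growth hormone-responsive genes had 8 of 14 lower and 2 higher under both adjustments (median -0.25, adjusted p = 0.00356, and 0.0566 with an estimated correlation), with Socs2, Egfr (-0.85 ± 0.25) and the growth hormone receptor gene Ghr (-0.69 ± 0.07) lower. Thyroid hormone-responsive and transport genes had 6 of 15 lower and 1 higher under both adjustments but the list was not called by camera (-0.11, adjusted p = 0.0583). Serpina7 and the thyroid hormone-binding Crym (-0.98 ± 0.08) fell and Me1 rose. Acute phase proteins had 9 of 19 lower and 3 higher, 9 and 4 when adjusted over the list alone (-0.12, adjusted p = 0.0026, and 0.0545 with an estimated correlation). A2m and Serpina3n (-0.87 ± 0.06) fell while Orm1 rose (0.74 ± 0.12).

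Cell cycle genes rose in number at 485 mg/kg, with 17 of 25 higher and 1 lower, 23 and 1 when adjusted over the list alone (median 0.37, adjusted p = 1.6e-07, and 0.071 with an estimated correlation). Cyclin A2 gene Ccna2 rose 2.10-fold (1.07 ± 0.25), Cdk1 rose 2.10-fold (1.07 ± 0.19) and the proliferation marker Mki67 rose 1.68-fold (0.75 ± 0.15). Heme synthesis and degradation had 4 of 10 higher, 5 higher and 1 lower when adjusted over the list alone (0.17, adjusted p = 0.00173, and 0.069 with an estimated correlation), with Alas1 (2.01 ± 0.18), Blvrb (1.02 ± 0.06) and heme oxygenase Hmox1 (0.67 ± 0.09). Heat shock genes had 4 of 8 higher under both adjustments (0.28, adjusted p = 0.0061, and 0.162 with an estimated correlation), among them the mitochondrial chaperonins Hspd1 (0.43 ± 0.05) and Hspe1 (0.39 ± 0.05). The mitochondrial respiratory chain had 6 of 20 higher and 1 lower, 9 and 1 when adjusted over the list alone (0.11, adjusted p = 0.0134, and 0.268 with an estimated correlation), with Ndufs1 (0.41 ± 0.05) and Uqcrc1 (0.22 ± 0.06) higher.

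Several stress and regulator lists were not called by camera at 485 mg/kg although single members were. Over all genes 2971 of 14217 were called at this dose, so a few called members do not mark a response of the list. The p53 and DNA damage list had 3 of 11 higher, Mdm2 (1.22 ± 0.12), Gadd45a (0.89 ± 0.27) and Plk2 (0.59 ± 0.12), and 1 lower, 3 and 2 when adjusted over the list alone (median 0.03, adjusted p = 0.539). The ER stress and amino acid response list had 5 of 22 higher and 1 lower, 6 and 3 when adjusted over the list alone (0.08, adjusted p = 0.316), with the serine synthesis enzyme Phgdh (0.76 ± 0.23) and the ER chaperone gene Sdf2l1 (0.37 ± 0.10) higher. Hepatic nuclear receptors had Ahr higher (0.76 ± 0.16) and the glucocorticoid receptor gene Nr3c1 lower (-0.62 ± 0.10) out of 14, the same count when adjusted over the list alone (-0.02, adjusted p = 0.802). Of 16 circadian clock genes 2 fell, Npas2 (-1.02 ± 0.35) and Nr1d1 (-0.41 ± 0.11), and 2 fell and 1 rose when adjusted over the list alone. The median of that list was 0.03, its mean was -0.02 and the test pointed downward (adjusted p = 0.884). Interferon and antigen presentation had 0 of 17 called under both adjustments (-0.06, adjusted p = 0.539).

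Markers of hepatocytes and of some other liver cells were lower at 485 mg/kg. Hepatocyte markers had 6 of 9 lower and 0 higher under both adjustments (median -0.18, adjusted p = 8.46e-05, and 0.017 with an estimated correlation), with Apoa1 (-0.31 ± 0.06) and Serpina1 (-0.25 ± 0.03). Fgb also fell (-0.31 ± 0.04, adjusted p = 1.64e-07), and this call for Fgb at 485 mg/kg was lost with the mean of its 3 probe sets (adjusted p = 0.0681), with its other alternatives at or below 9.15e-07. Periportal hepatocyte markers had 5 of 8 lower and 0 higher, 5 and 1 when adjusted over the list alone (-0.76, adjusted p = 0.000429, and 0.0231 with an estimated correlation), with Pck1, Sds and Hal, which also stand on the metabolic lists. Pericentral hepatocyte markers had 2 of 8 lower and 1 higher, 5 and 1 when adjusted over the list alone (-0.19, adjusted p = 0.0173, and 0.196 with an estimated correlation). Oat and glutamine synthetase Glul (2.43-fold lower, -1.28 ± 0.11) fell and Cyp1a2 rose.

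Kupffer cell and macrophage markers had 4 of 9 lower and 0 higher at 485 mg/kg, 7 when adjusted over the list alone (median -0.40, adjusted p = 0.00445, and 0.386 with an estimated correlation). Clec4f (-0.62 ± 0.18), Cd163 (-0.54 ± 0.13) and Csf1r (-0.52 ± 0.14) fell. Sinusoidal endothelial markers had 2 of 9 lower, Kdr (-0.43 ± 0.08) and Pecam1 (-0.27 ± 0.09), and 5 when adjusted over the list alone (-0.21, adjusted p = 0.016, and 0.253 with an estimated correlation). T and NK cell markers had 3 of 10 lower, with Ptprc at -0.55 ± 0.18 and Cd8a at -0.53 ± 0.10, and 4 when adjusted over the list alone (-0.18, adjusted p = 0.0256, and 0.268 with an estimated correlation).

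The remaining marker lists were not called by camera at 485 mg/kg. Erythroid markers had 2 of 4 lower under both adjustments (median -0.33, adjusted p = 0.0623), Hbb (-0.77 ± 0.14) and Alas2 (-0.55 ± 0.19, adjusted p = 0.0417). The call for Alas2 at 485 mg/kg was lost after median centring (adjusted p = 0.0504), and its alternatives ran from 0.0403. Stellate cell and fibroblast markers had Rgs5 higher (0.81 ± 0.15) and 1 gene lower out of 12, the same count when adjusted over the list alone (-0.09, adjusted p = 0.685). Cholangiocyte markers had Epcam higher (0.60 ± 0.10) out of 6, with a median of -0.07, a mean of 0.03 and a test pointing upward (adjusted p = 0.813). B cell markers (-0.24, adjusted p = 0.185) had 0 of 4 called and 1 lower when adjusted over the list alone, and neutrophil markers (-0.10, adjusted p = 0.372) had 0 of 6 under both adjustments. Pancreatic acinar markers had 1 of 8 lower, Cela1 (-0.67 ± 0.17), with a median of -0.04 (adjusted p = 0.33). Adipocyte markers had 1 of 5 lower, Cfd (-0.43 ± 0.11), with a median of 0.01, a mean of -0.06 and a test pointing downward (adjusted p = 0.491).

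**Figure D3:**
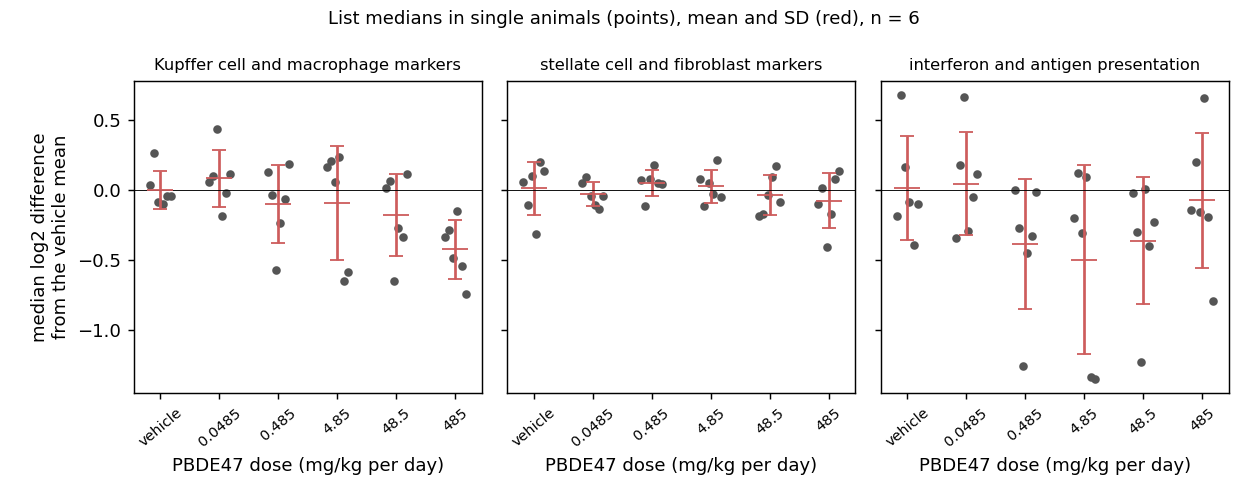
Median log2 difference from the vehicle mean of 3 gene lists in single animals (grey points), with the group mean and SD in red, for vehicle and each PBDE47 dose in mg/kg (n = 6). The macrophage list stands at -0.42 ± 0.21 at 485 mg/kg, and 4 animals at 0.485, 4.85 and 48.5 mg/kg lie lowest for the interferon list, at -1.23 or below.

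**Figure D4:**
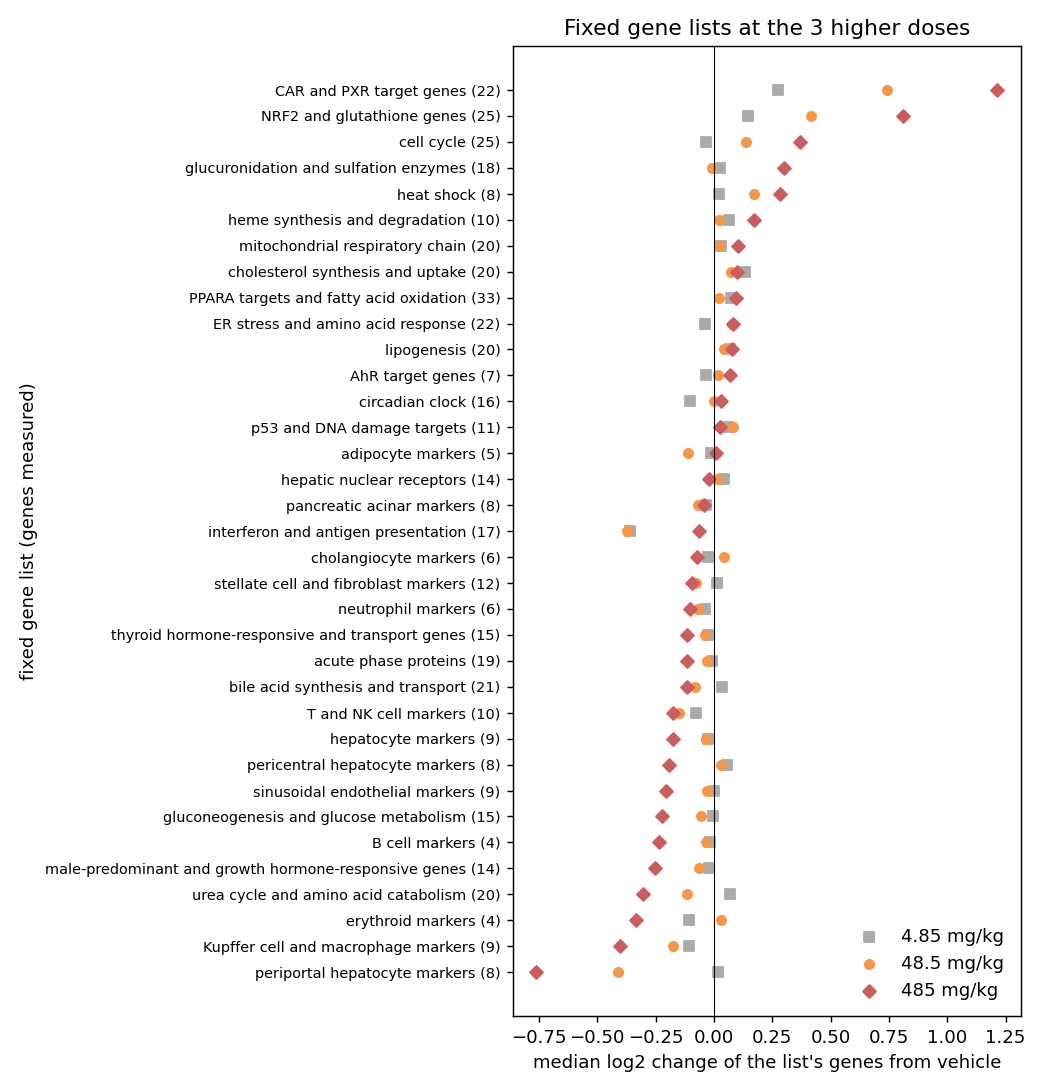
Median log2 change from vehicle of the genes of each of 35 fixed lists at 4.85 (grey squares), 48.5 (orange circles) and 485 mg/kg (red diamonds), with the number of measured genes in brackets and n = 6 animals per group. CAR and PXR targets stand highest at 485 mg/kg at 1.22 and periportal hepatocyte markers lowest at -0.76.

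Between 48.5 and 485 mg/kg several genes of drug metabolism rose strongly while the CYP2B joint probe set changed little. Cyp1a1 rose another 10.7-fold (log2 3.42 ± 0.26 SE, adjusted p = 4.77e-11), Sult2a6, which was not called at 48.5 mg/kg, rose 5.60-fold (2.48 ± 0.30, adjusted p = 6.36e-07), Gsta3 rose 3.48-fold (1.80 ± 0.17, adjusted p = 3.67e-09), Ttc39a rose 3.43-fold (1.78 ± 0.13, adjusted p = 3.55e-11) and Ces2c rose 3.09-fold (1.63 ± 0.13, adjusted p = 2.35e-10). Dhrs7l1 (-2.47 ± 0.33), Nox4 (-1.79 ± 0.20), Serpina7 (-1.69 ± 0.35), A2m (-1.63 ± 0.31) and Slc6a6 (-1.62 ± 0.40) fell between these doses, with adjusted p values from 1.63e-07 to 0.0111, and none of these was called lower at 48.5 mg/kg than in vehicle. The CYP2B joint probe set differed by 0.19 ± 0.17 (95% interval -0.15 to 0.54, adjusted p = 0.666) and Ugt2b1 by 0.20 ± 0.11 (adjusted p = 0.402), with errors from the spread within all 6 groups. Within these 2 groups the spread of the CYP2B joint probe set was narrower (SD 0.05 and 0.07, against 0.41 in vehicle and 0.60 at 0.485 mg/kg). Its 6 values at 485 mg/kg (14.35 to 14.55) all lay slightly above its 6 at 48.5 mg/kg (14.18 to 14.32), so a small rise is not excluded by the test. The spread of Ugt2b1 was narrower in these groups too (SD 0.10 and 0.06, against 0.23 in vehicle), so the same limit holds for it.

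In the rest of the panel, Abcc3 (1.28 ± 0.15), Nqo1 (1.32 ± 0.12) and Cyp3a23-3a1 (0.36 ± 0.10, adjusted p = 0.0283) rose between 48.5 and 485 mg/kg. Cyp2c11 (-0.20 ± 0.06, adjusted p = 0.0592), Dio1 (-0.22 ± 0.09, adjusted p = 0.173), Cyp7a1 (-0.39 ± 0.27, adjusted p = 0.544), Cyp1a2 (0.10 ± 0.08, adjusted p = 0.574) and Thrsp (0.16 ± 0.31, adjusted p = 0.885) did not pass. In all, 792 probe sets were higher and 717 lower at 485 than at 48.5 mg/kg, 1509 together, with 4909 at an unadjusted p under 0.05. The number of probe sets changed between 485 and 48.5 mg/kg was 880 in a fit on the 12 arrays of these doses alone.

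Camera at the preset correlation called 21 of 35 lists between these doses, and 7 held with an estimated correlation. Among the 7, CAR and PXR targets had 12 of 22 genes higher and 0 lower, 16 when adjusted over the list alone (median 0.40, adjusted p = 7.99e-18, and 0.00172 with an estimated correlation), and NRF2 and glutathione genes had 20 of 25 higher and 0 lower, also when adjusted over the list alone (0.54, adjusted p = 1.79e-31, and 2.96e-05 with an estimated correlation). AhR targets had 2 of 7 higher under both adjustments, Cyp1a1 and Nqo1 (0.06, adjusted p = 0.00385, and 0.0425 with an estimated correlation). Glucuronidation and sulfation enzymes had 6 of 18 higher and 4 lower, 7 and 4 when adjusted over the list alone (0.15, adjusted p = 0.0056, and 0.0425 with an estimated correlation). Acute phase proteins had 5 of 19 lower and 1 higher, 9 and 1 when adjusted over the list alone (-0.09, adjusted p = 0.00101, and 0.039 with an estimated correlation). Male-predominant and growth hormone-responsive genes had 3 of 14 lower and 1 higher, 7 and 1 when adjusted over the list alone (-0.19, adjusted p = 0.00179, and 0.0425 with an estimated correlation). Hepatocyte markers had 3 of 9 lower and 0 higher, 6 when adjusted over the list alone (-0.12, adjusted p = 9.8e-05, and 0.0164 with an estimated correlation). Of the other lists 6 were called higher (PPARA targets, heat shock, cell cycle, interferon, heme and respiratory chain genes) and 8 lower (bile acid, gluconeogenesis and urea cycle genes and pericentral, periportal, macrophage, endothelial and erythroid markers), with adjusted p values from 9.72e-07 to 0.0439, and from 0.0948 to 0.719 with an estimated correlation.

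Most probe sets called at 48.5 mg/kg were called again at 485 mg/kg in the same direction. Of 1052 probe sets, 908 (86.3%) were called at both doses, 704 higher and 204 lower at both, and 0 were called in opposite directions. Independent lists of these sizes would share 80.6. The log2 changes correlated with r = 0.75 across all probe sets, which are not independent replicates, against a median of 0.48 and a highest of 0.67 in 100 simulated draws of unchanged groups that shared their controls. With the vehicle arrays split between the comparisons, fewer controls were left and a median of 433 probe sets were called at 48.5 mg/kg and 3211.5 at 485 mg/kg. The overlap then had a median of 352.5 and ranged from 251 to 504 over 20 assignments, with a median correlation of 0.54. It is to be read against those 433 calls and not against 1052. Of the probe sets called at both 48.5 and 485 mg/kg, 77.5% were higher, and 67.0% after quantile normalization of the deposited values.

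Of the 1052 probe sets called at 48.5 mg/kg, 759 (72.1%) had a larger change in the same direction at 485 mg/kg. The direct test between the doses called 321 of them further in that direction and 13 back toward vehicle.

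**Figure D5:**
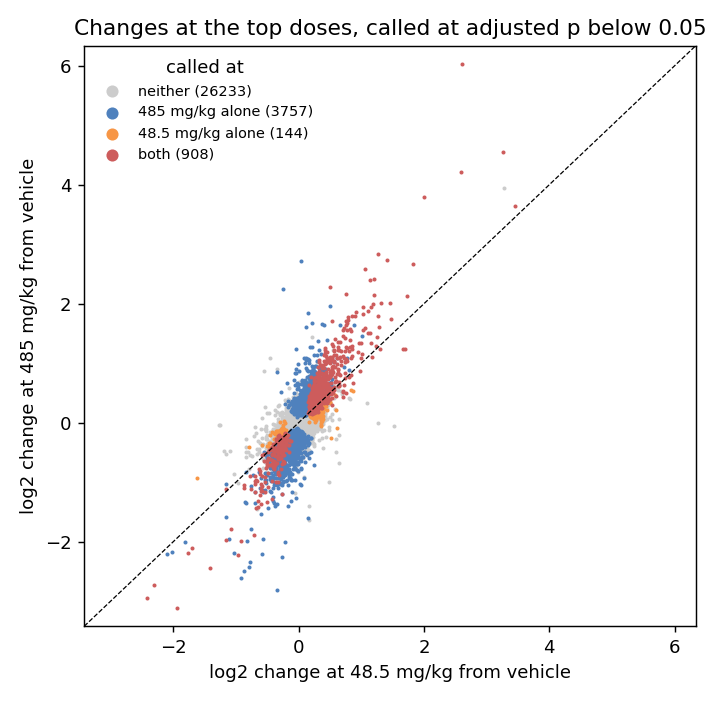
Log2 change from vehicle of 31042 probe sets at 48.5 mg/kg (horizontal) and at 485 mg/kg (vertical), coloured by the dose at which limma called them, with the line of equal change dashed (n = 6 per group). The 908 probe sets called at both doses changed in the same direction at both. Many lie near the centre, as the median absolute log2 change of all calls at 48.5 mg/kg was 0.32.

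The 3' minus 5' differences did not separate the dose groups from vehicle after adjustment, while the first principal component did at the 2 highest doses. Of 30 exact two-sided permutation tests, on 3' minus 5' differences of Gapdh, Actb and hexokinase and on 3 principal components at 5 doses, only the first component at 48.5 and 485 mg/kg passed the adjustment (exact p = 0.00216, the smallest that 924 assignments give to 3 digits, adjusted p = 0.0325 for each). That component held 19.9% of the variance. Its mean was -11.5 ± 2.43 (SD) in vehicle, 8.47 ± 2.74 at 48.5 mg/kg and 29.8 ± 4.59 at 485 mg/kg, so it follows dose. The labels give no scan date or batch, so none could be compared.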

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

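The tests of RNA quality and dose assignment for 1 array, of a receptor plateau and of both explanations for the macrophage list were chosen only after the result was seen.

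In a group of 6 animals, 1 value far from the other 5 was sought in 343 groups of values from 111 genes and 7 array measures. It was found in 24 groups, and chance alone gives about 17.2 at 1 in 20. Values below are log2 levels with the range of the other 5 animals.

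Among genes of drug metabolism and hormone response, Cyp1a1 was at 9.36 in 485 mg/kg replicate 1 (others 10.91 to 11.56), and Cyp1a2 at 13.65 in vehicle replicate 5 (13.10 to 13.26). Dio1 was at 6.98 in 0.0485 mg/kg replicate 5 (7.35 to 7.41), Cyp7a1 at 10.54 in 4.85 mg/kg replicate 1 (11.63 to 12.16) and Cyp2c11 at 13.37 in 0.485 mg/kg replicate 6 (13.70 to 13.87). The CYP2B joint probe set was at 10.02 in vehicle replicate 3 (10.77 to 11.19), and Gsr at 8.56 in the same animal (8.80 to 8.87).

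Among other genes in treated animals, Dexi was at 7.58 in 48.5 mg/kg replicate 2 (7.80 to 7.91), Pdia5 at 6.91 in replicate 1 (7.36 to 7.58), Abcg8 at 4.95 in replicate 5 (6.07 to 6.52) and Rgs5 at 5.69 in replicate 4 (6.47 to 6.72) of the same dose. At 485 mg/kg Acot2 was at 10.43 in replicate 4 (9.84 to 10.04) and Hal at 7.85 in replicate 2 (8.93 to 9.27).

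In vehicle animals, Abcg8 was at 5.99 (7.07 to 7.53), Ccna2 at 5.48 (3.97 to 4.33) and Cfd at 7.77 (7.96 to 8.05), all in replicate 5. Nr1d1 was at 7.08 (7.57 to 7.84) and Ahr at 4.84 (5.37 to 5.65) in replicate 6, and Pecam1 at 6.27 in replicate 1 (6.69 to 6.81). Among array measures, the 3' minus 5' difference of Actb was 1.04 in 0.0485 mg/kg replicate 3 (1.20 to 1.28), and that of hexokinase was 1.00 in 0.485 mg/kg replicate 1 (1.20 to 1.31).

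The array of 4.85 mg/kg replicate 6 stood apart from the other 5 of its group on the second component (-25.7, others -5.49 to 1.99), the third component (-27.2, others 3.16 to 13.9) and the SD of its residuals (0.238, others 0.147 to 0.156). Degraded RNA is argued against by its 3' minus 5' difference of 0.729, within 0.577 to 0.896 on the other 35 arrays, and a wrong dose by its CYP2B joint probe set level of 13.12, within 12.78 to 13.13 in its group. After quantile normalization of the deposited values its residual SD was 0.232, against 0.137 to 0.193 on the other arrays. RMA had already normalized the probes between arrays, so this step could change little. It does not decide on an array-wide difference in signal distribution. The upper quartile of this array, at 7.24, was the lowest of all arrays. Of the 98 probe sets that lay highest on this array among its 200 farthest, 71.4% were unnamed, against 31.5% of all. Over the 200 together, higher and lower, 43.5% were unnamed. No biological explanation was tested, and what set this array apart stays open.

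The CYP2B joint probe set reached nearly the same level at 48.5 and 485 mg/kg, with 94.7% of its log2 change present at the lower dose, against a median of 49.9% over 146 probe sets at least 2-fold higher. Not every target levelled off: of the 20 CAR and PXR list genes called higher at 485 mg/kg, 12 were also called higher there than at 48.5 mg/kg, and 0 lower. This does not decide on a plateau of the receptor response. The genes were chosen by their call at 485 mg/kg, and some of the 12, such as Gstm1 and Akr7a3, also stand on the NRF2 list. Among those not called between the doses were Ugt2b1 (0.20 ± 0.11 SE), Cyp2c6v1 (0.07 ± 0.04), Cyp3a2 (0.07 ± 0.05) and Cyp3a9 (-0.46 ± 0.26). Saturation of the probe signal cannot be told apart from a true levelling off of these genes: the share of the change present at 48.5 mg/kg had a Spearman rho of 0.27 with level across probe sets, between the bounds set for either reading. At 485 mg/kg 13 probe sets had a higher mean level, which does not decide whether this one was saturated. A limit of this gene pair alone stays open and was not tested.

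The macrophage marker list was lower at 485 mg/kg, with a shift of -0.43 in the mean of its medians per animal, with 6 of 6 animals below the vehicle range (exact permutation p = 0.00216, the smallest possible to 3 digits). The difference between macrophage and cholangiocyte medians changed by -0.41 against vehicle (exact p = 0.00866, adjusted p = 0.0325 over 5 lists). This argues only against an equal fall of all 5 other lists. The difference from T and NK cell markers was -0.26 (exact p = 0.0130), while those from stellate (-0.34, exact p = 0.0801), endothelial (-0.22, exact p = 0.225) and erythroid markers (-0.03, exact p = 0.777) did not pass. By their own medians per animal, erythroid (-0.40, exact p = 0.00649), endothelial (-0.21, exact p = 0.0173) and T and NK cell markers (-0.17, exact p = 0.0433) were lower than in vehicle too. Stellate (-0.09, exact p = 0.448) and cholangiocyte markers (-0.01, exact p = 0.82) did not pass. A fall shared by several cell types other than hepatocytes therefore stays open. Low interferon gene levels of single animals are argued against as the whole source, since the interferon list median at 485 mg/kg lay near that of vehicle (-0.08, exact p = 0.725). With these levels as a covariate the shift was -0.38 ± 0.069 (SE), and -0.43 ± 0.156 without. That fit adds little, because a covariate so alike in both groups could remove little of the shift. A smaller number of macrophages and lower expression per cell both stay open, and neither was tested.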

How the results depend on the processing

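The fits without the array of 4.85 mg/kg replicate 6 in any comparison were chosen only after the data were seen, and all other alternatives before.

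Under the replicate block, both scalings, the brightness filter, the ordinary test, the trend and robust setting and the array weights, the number of probe sets changed at 48.5 mg/kg ran from 980 to 1415, that of probe sets changed at 485 mg/kg from 4523 to 4931 and that at 4.85 mg/kg from 6 to 7, and it was 0 at 0.0485 and 0.485 mg/kg. The replicate block kept 977 of the 1052 calls at 48.5 mg/kg and 4517 of 4665 at 485 mg/kg, and quantile normalization kept 851 and 4313. Median centring moved the median over all probe sets of a comparison by at most 0.0175. After quantile normalization that median was -0.0029 at 48.5 mg/kg and -0.0024 at 485 mg/kg, against -0.0102 and -0.0116 in the main fit.

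Fits on only the 12 arrays compared estimate the spread from fewer arrays, and gave 1 for probe sets changed at 4.85 mg/kg, 556 for probe sets changed at 48.5 mg/kg and 880 for probe sets changed between 485 and 48.5 mg/kg. A minimum change of 1.5-fold is a stricter criterion, and left 150 probe sets changed at 48.5 mg/kg and 797 probe sets changed at 485 mg/kg. The ordinary unmoderated test gave 0 probe sets with a trend over vehicle and the 3 lowest doses, and the cause was not tested. With the vehicle arrays split 3 and 3, which leaves fewer controls, a median of 352.5 probe sets were called at both 48.5 and 485 mg/kg. The median number called at 48.5 mg/kg in these splits was 433.

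Leaving out single arrays gave 678 to 1138 probe sets changed at 48.5 mg/kg (678 without replicate 5 of this dose), 5 to 8 at 4.85 mg/kg, 4130 to 4549 at 485 mg/kg and 1 to 3 with a trend (1 without vehicle replicate 2 or 4.85 mg/kg replicate 4). Without 4.85 mg/kg replicate 6 in any fit there were 1165 probe sets changed at 48.5 mg/kg and 4908 probe sets changed at 485 mg/kg.

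Of the gene lists, camera with an estimated correlation called 0 fixed gene lists shifted at 0.0485 mg/kg, 0 at 0.485 mg/kg, 1 at 4.85 mg/kg, 3 at 48.5 mg/kg and 5 at 485 mg/kg, since this setting lets correlated genes count for less. Fry called 0 at 0.0485 mg/kg, 0 at 0.485 mg/kg and 2 at 4.85 mg/kg, but 11 at 48.5 mg/kg and 23 at 485 mg/kg, against 11 and 20 by camera at the preset correlation. At 485 mg/kg fry added the thyroid hormone (adjusted p = 0.000115), p53 (0.0348), B cell (0.0138) and erythroid lists (0.00132) and lost the bile acid list (0.165). Fry does not set a list against the other genes, so it answers another question than camera. Only brighter probe sets gave 1 list at 0.0485 mg/kg. The cause was not tested for fry or for this filter.

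Of 652 values of named genes under alternatives, 631 kept their sign and their side of the threshold, 18 lost a call, 1 gained one and 2 changed sign. The sign changes were those of Cyp1a1 at 0.0485 mg/kg, at 0.018 after quantile normalization and 0.011 after median centring, for a gene whose mean was the same in both groups to 2 decimals; the cause was not tested. Signal over background limits transcripts of low level, and no filter on level was applied outside the brightness alternative.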

Other observations

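The test of interferon and macrophage lists between animals was chosen only after the result was seen.

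Each count was compared with 100 splits of its arrays into groups of the same sizes, the real one included. At 4.85 mg/kg 1 split, the real one with 6 calls, gave as many, and the highest other gave 5. By the bound set beforehand, a rank below the 0.05 level, this would exclude chance. Simulated groups without an effect, a comparison outside that bound, gave up to 14 called probe sets at 485 mg/kg, so a count of 6 does not by itself exclude chance. This concerns the count and not each call, since the CYP2B joint probe set had a limma adjusted p of 2.83e-10 at 4.85 mg/kg. Chance can be excluded at the 0.05 level at 48.5 mg/kg (1 split, real 1052, highest other 103), at 485 mg/kg (1 split, 4665 against 1758), between these doses (1 split, 1509 against 226) and among the 6 groups (1 split, 4041 against 3). For the trend the real split also ranked first (1 split, 2 against 1), which meets the same bound. Its count was 1 without vehicle replicate 2 and 0 by the ordinary test, so chance is not excluded there. For the overlap of 48.5 and 485 mg/kg 1 split, the real one with 908, gave as many and the highest other gave 0, but the median call count of the other splits at each of these doses was 0, leaving little to share, so this adds nothing to the counts at each dose. At 0.0485 and 0.485 mg/kg the real count was 0 by limma, with 1519 and 1381 probe sets at an unadjusted p under 0.05 and 0 by the ordinary test, so 100 of 100 splits gave as many, with a highest other of 1 at each dose.

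For gene lists at the preset correlation, chance was not excluded at 0.0485 mg/kg (36 of 100 splits gave as many as the real 5, highest other 8), at 0.485 mg/kg (27 splits, real 5, highest 8), at 4.85 mg/kg (36 splits, real 6, highest 11) or at 48.5 mg/kg (6 splits, real 11, highest 13). At 485 mg/kg 4 of 100 splits gave as many as the real 20, with a highest other of 21. That rank lies just below the 0.05 level and was not adjusted over the doses, so it is weak evidence against chance. The preset correlation called up to 9 lists in simulated groups without an effect, so these counts are a weak test and do not decide on single lists. An estimated correlation called at most 1 in such groups. With it CAR and PXR targets were called at 4.85 mg/kg (camera adjusted p = 0.00255) and at 48.5 mg/kg (2.67e-05).

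Interferon and macrophage genes varied together between animals of the same dose group, which may reflect a shared state of single animals apart from dose. A low cluster of 4 animals (0.485 mg/kg replicate 3, 4.85 mg/kg replicates 5 and 6, and 48.5 mg/kg replicate 3) had interferon list medians at or below -1.23, against -0.80 or above in the other 32. Among these 32, the deviations of the 2 list medians from their group means correlated with Pearson r = 0.76 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman rho = 0.70 (permutation p = 5e-05), and r was 0.70 without the 2 animals farthest from the median. This was 1 relation computed, and the source of such a state was not tested.

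Replicate numbers did not pair the arrays across groups. The correlation of residuals across probe sets had a median of 0.0105 for arrays of the same number and -0.0043 for others, and 0 of 36 arrays correlated best with its own number in every other group.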
